A study of Homo sapiens with 10 samples.

How the data were processed

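Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in DLD-1 cells, an established human colorectal adenocarcinoma line. Per the labels, 10 libraries form 5 groups of 2. A line with GATA6 fused to an auxin-inducible degron, a tag that marks the protein for destruction when auxin (IAA) is present, gave the groups AID_ctrl (labelled as treated with auxin but with a time of 0 h and a title of control, and read as untreated), AID_aux (12 h) and AID_wash (auxin washed out, with a time label of 1 and no unit). The labels' protocol gives 500 µM IAA. Unedited cells (WT) and cells in which CRISPR/Cas9 had disrupted GATA6 (KO) gave the other 4 libraries. The labels' protocol states the Omni-ATAC method on 50000 viable cells and 150-nt paired reads. The labels do not say whether replicates were separate cultures, so differences between replicates measure only the spread between these samples, which may be technical.

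Trim Galore 0.6.10, Bowtie2 2.4.2, Picard, MACS2 2.1.1 and the genome build hg38 are named in the submitters' processing notes. Their parameters, the handling of the transposase offset and any filter on blacklisted regions are not given in the sources used here. Peaks were listed separately for each library. In the 6 deposited degron lists each line is a peak summit with its interval, and several summits can share an interval. These deposited lists carry a score per peak, which equals 10 times the −log10 p, cut to a whole number and held at 1000, a fold enrichment ratio per peak, and the −log10 of a p-value and of a q-value per peak. The smallest deposited −log10 p was 5.00 in all 6 degron lists, and some peak numbers are absent from them, by a rule not given in the sources used here. The 4 deposited WT and KO lists hold coordinates only: windows of exactly 500 bp that do not overlap, with no score, ratio or p-value. The score, ratio and −log10 values are the authors' own values within one list and were used only to rank or filter peaks within that list. The deposited coordinates are in hg38, and positions are given here counted from 1. The files hold no read counts, so sequencing depth is unknown, and the number of peaks and the length they cover are the measures of how much was called. No other per-sample value was used.

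Peaks on chromosomes 1 to 22 and X were merged into regions wherever intervals overlapped or touched, over the 6 degron lists for the comparisons within the degron line and over the 4 WT and KO lists for the knockout. A library called a region when at least 1 of its peaks overlapped it by 1 bp. For each of 4 comparisons (AID_aux against AID_ctrl, AID_wash against AID_aux, AID_wash against AID_ctrl, KO against WT), a region was lost when both reference libraries called it and neither library of the other group did, gained in the reverse case, and retained when all 4 libraries called it. Because 2 libraries against 2 can be split in only 3 ways, no p-value was given for these counts. The counts from the other 2 ways to pair the same 4 libraries served as the background: both replicate 1 libraries against both replicate 2 libraries, and the crossed pairs. Regions that lay in the top 50% of both calling lists by −log10 p were also counted alone and are called strong. This count was planned as an alternative and was given its place in the text after its result was seen.

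Position was described by nearness to gene ends. The gene table used here (RefSeq, GRCh38.p14) gives the start and end of each gene without strand or exons, so a promoter could not be told from the other end of a gene, nor an exon from an intron. A region was near a gene end when it lay within 1000 bp of either end of any protein-coding gene. It was assigned to the protein-coding gene whose body was nearest to its midpoint, within 100000 bp. Fisher's exact test, two-sided, compared changed with retained regions. For the degron lists a Mantel-Haenszel odds ratio within deciles of the peak rank, the position of regions picked by the other pairings, the counts of those pairings with equal list lengths and under the settings for strong regions, and the return by direction were added after the data were examined. The return after wash was the share of changed regions that the 2 wash libraries called or did not call, with Wilson intervals at 95% that cover counting error only. The overlap between degron and knockout was a Mantel-Haenszel odds ratio with its 95% interval, among regions decided in both comparisons, within deciles of the AID_ctrl rank (AID_aux for gains) and nearness to a gene end. The expected overlap of independent lists was given beside it. These 2 comparisons share no library. Regions are not replicates, and p-values and intervals over regions describe these lists.

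For 17 gene lists with 431 genes, all of which matched the gene table, the number of lost and of gained regions was compared, two-sided, with 10000 random lists of the same size matched on the number of tested regions per gene. Benjamini-Hochberg adjustment covered the 34 tests of a comparison. The lists were endoderm and intestinal transcription factors, WNT targets and stem cell genes, enterocyte and colonocyte genes, goblet and secretory genes, enteroendocrine genes, BMP and TGF-beta pathway, mesenchymal genes, epithelial junction and keratin genes, squamous and basal genes, YAP targets and fetal intestine genes, NF-kB and interferon genes, aryl hydrocarbon receptor targets, cohesin, CTCF and looping factors, housekeeping genes, cell cycle genes, and markers of blood and immune cells and of fibroblasts and endothelium. Comparisons, tests, lists and the rule for named genes were fixed before the data were examined. For AID_aux against AID_ctrl and KO against WT the rule named GATA6, the 10 genes with most lost and the 10 with most gained regions (ties by the share of the gene's regions), the 2 genes of each list with most changed regions, and the 5 lost and 5 gained regions of highest mean rank. The last part applied only to the degron lists, since the WT and KO lists carry no rank. Some genes that the rule names are not reported here.

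Several planned steps were changed. Tests of GATA motifs were not run because no genome sequence was used here. Distances to transcription start sites became distances to gene ends and gene bodies, and the setting of a gene body with 5 kb upstream became 5 kb on either side. Strata on WT scores became strata on degron ranks. Settings that need scores were not run on the WT and KO lists. Alternatives tried were only peaks with −log10 q of at least 5, equal list lengths, peaks that cover at least 50% of a region, fixed windows of 501 bp, regions from the 4 compared libraries only, other distances, each replicate left out, and a replicate block for the overlap.

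The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, bedtools 2.31.1 and matplotlib 3.10.9. Merging, overlap and odds ratios were checked against bedtools and statsmodels. The counting was tested on simulated data for AID_aux against AID_ctrl with 120452 regions. Strengths were means of the AID_ctrl libraries, with a −log10 p just under the calling threshold assumed where a library did not call the region. Replicate noise was taken from the regions that both AID_ctrl libraries called. In the second group 100 regions had their −log10 p lowered 4-fold and 100 had it lowered 8-fold. Of these, 40 and 52 were called lost. Among the 50 and 58 that were strong, 0 and 12 were called lost. Strong meant here a score at or above the median of the called regions. That bound is stricter than in the data, where 52901 of the 89608 regions called by AID_ctrl replicate 1 lay in the top 50%. The recovery in the simulation therefore does not carry over to the counts of strong losses in the data. Among unchanged simulated regions 2119 were called lost and 2073 gained, and 0 strong regions were called lost. The 2119 and 2073 depend on the value assumed for uncalled regions. The list test gave an unadjusted p under 0.05 for 2.50% of 200 random lists.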

Results

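Open chromatin was mapped by ATAC-seq in DLD-1 colorectal cancer cells in which the transcription factor GATA6, a zinc-finger protein of endoderm and gut epithelium, was removed either quickly, by an auxin-inducible degron, or lastingly, by CRISPR knockout. The degron line was sampled before auxin (AID_ctrl), after 12 h of auxin (AID_aux) and after auxin had been washed out (AID_wash). The labels of AID_ctrl name auxin as the treatment with a time of 0 h and a title of control, and these libraries were read as untreated. The knockout (KO) was compared with unedited cells (WT). Each of the 5 groups had 2 libraries. The deposited peak lists held 191535 and 179405 peaks for AID_ctrl replicates 1 and 2, 199036 and 173618 for AID_aux, 154537 and 180018 for AID_wash, 93104 and 66078 for WT, and 130807 and 116626 for KO. They covered 69.3 and 65.6 Mb in AID_ctrl, 70.2 and 62.6 Mb in AID_aux, 56.7 and 64.3 Mb in AID_wash, 46.4 and 33.0 Mb in WT, and 65.2 and 58.1 Mb in KO. The degron lists merged into 120452 regions and the WT and KO lists into 157584 regions.

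Most of the open chromatin of the degron line was shared between conditions. The Jaccard index of covered bases, the shared length divided by the joint length, was 0.708 between the AID_ctrl replicates, 0.705 between the AID_aux replicates and 0.693 between the AID_wash replicates. Between AID_aux and AID_ctrl libraries it was 0.682 to 0.697, only slightly below the values within groups. The KO replicates had a Jaccard index of 0.639 and the WT replicates one of 0.398, and pairs of a KO and a WT library ranged from 0.273 to 0.444. The WT replicates thus differed from each other about as much as WT differed from KO.

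At the GATA6 gene itself (chromosome 18, 22169589 to 22202528) and its surroundings, 35 regions of the degron lists were assigned to the gene. AID_ctrl libraries called 25 and 25 of them, AID_aux 26 and 20, and AID_wash 19 and 22, and 13 were called in all 6 libraries. Of 33 regions in the WT and KO lists, WT called 19 and 15 and KO 29 and 26, with 12 called in all 4. Calls at the locus check neither the degron nor the knockout, since protein removal leaves the gene in place and a small edit need not close its chromatin.

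The first comparison asked which regions closed or opened within 12 h of auxin. A set of strong regions lost its calls: 190 regions in the top 50% of both AID_ctrl lists were called by neither AID_aux library. Another 10 strong regions were gained. Depth is unknown, so a region without a call may still be open below the calling threshold. The highest-ranked lost region lay on chromosome 3 (193978129 to 193979109), 91380 bp from LOC102724877. The next was on chromosome 2 (30290258 to 30291422), 30811 bp from LBH, a transcription cofactor gene. Others lay on chromosome 8 (38075956 to 38077049), 16137 bp from EIF4EBP1, which encodes a repressor of translation controlled by mTOR, and on chromosome 11 (102191727 to 102193224), inside YAP1, the effector of the Hippo pathway. The fifth was on chromosome 1 (232682304 to 232682854), 52082 bp from SIPA1L2.

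The other ways of pairing the same 4 libraries gave 5 strong regions called by both replicate 1 libraries and neither replicate 2 library, 0 in reverse, and 1 and 4 for the crossed pairs. The 190 strong losses were therefore far above the spread between replicates, and the 10 strong gains were close to it. Losses exceeded the other pairings under each setting run for strong regions, by less in the wider ones: with the top 30% of each list 41 were lost and 0 gained (other pairings 0), with the top 70% 627 and 240 (up to 183), with peaks covering at least 50% of a region 963 and 368 (up to 591), and with fixed windows 269 and 22 (up to 29). Of these 4 settings, gains exceeded the other pairings only with the top 70%. With a library left out, fewer libraries have to concur and the counts rise: strong losses were 308 without AID_ctrl replicate 1, 369 without AID_ctrl replicate 2, 469 without AID_aux replicate 1 and 267 without AID_aux replicate 2, and strong gains were 90, 69, 52 and 120 in the same order.

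At any strength 2729 regions were lost, 2974 were gained and 68803 were retained. Both replicate 1 libraries called 2756 regions that neither replicate 2 library called, with 903 in reverse, and the crossed pairs gave 1037 and 2169. The lost count was thus below the highest of these and the gained count above it, and the total of 5703 exceeded the totals of 3659 and 3206 of the other pairings. With equal list lengths 2738 were lost and 2667 gained, where the other pairings gave 1228 to 1745. Replicate differences can therefore supply a large part of these regions, and the counts at single genes that follow, which are at any strength, include such background. Without AID_ctrl replicate 1, AID_ctrl replicate 2 or AID_aux replicate 1 the lost count was 7149, 7929 or 7082, and without AID_aux replicate 2 it was 3965. The gained count was 6468, 5621, 7073 and 11585 in the same order.

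**Figure D1:**
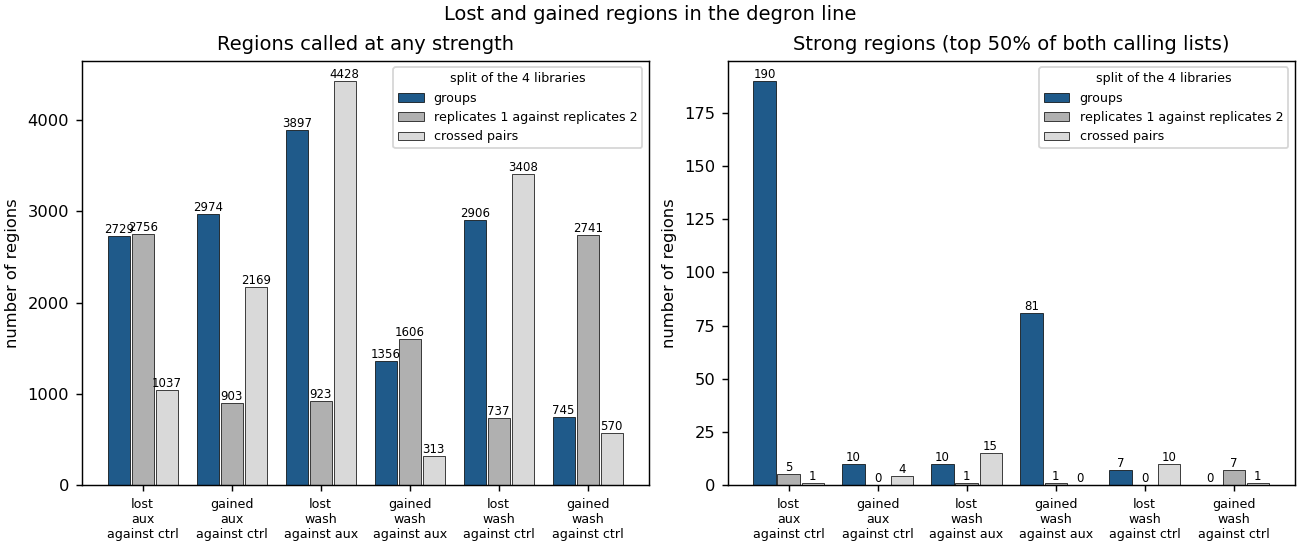
Number of lost and gained regions (vertical axis, regions) in the 3 comparisons within the degron line, for the true groups (blue) and the other 2 pairings of the same 4 libraries (greys), at any strength (left) and for strong regions only (right). Among strong regions, the 190 lost with auxin and the 81 gained after wash exceed the counts of the other pairings, which reach 5 and 15 in either direction. At any strength the 2729 regions lost with auxin lie below, and the 2974 gained above, the 2756 of an other pairing.

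GATA6 had 2 lost, 2 gained and 15 retained regions. Most lost regions were assigned to MACROD2 (7 lost, 1 gained, 20 retained), a very long gene, then to KCNQ5, a potassium channel gene (5, 2 and 16), and FAT1, an atypical cadherin (5, 3 and 21). RASSF8, RBMS3, CACNA2D3, DNM3 and the polarity gene PARD3 each had 4 lost regions, against 10, 14, 17, 18 and 32 retained. MMRN1 had 3 lost and 1 retained, and TBCK 3 lost and 2 retained. Among the genes with many gained regions, PRR5, EPAS1 (the hypoxia factor HIF-2α), EBF2, HDAC9, CNTNAP2, BCAS3, RPS6KA2 and MAGI2 had 4 gained regions each, against 8, 9, 10, 11, 13, 16, 18 and 19 retained. Long genes hold many regions and can collect many changes by number alone.

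None of the 34 list tests passed for AID_aux against AID_ctrl (smallest adjusted p = 0.669, permutation test), and 1 had an unadjusted p under 0.05. Enteroendocrine genes had 5 lost regions where 1.52 were expected (unadjusted p = 0.0316, permutation test), of which NTS, the neurotensin gene, had 2. Among intestinal transcription factors 12 of 256 tested regions were lost (10.2 expected) and 10 were gained (10.8 expected). CDX2, a master regulator of intestinal identity, had 2 lost, 1 gained and 6 retained. The WNT target list had 4 lost and 8 gained regions (7.79 and 8.47 expected), with CCND1 and EPHB2 at 1 lost and 1 gained each. Enterocyte genes had 4 lost and 2 gained (3.21 and 3.50 expected), with 1 lost at APOB and 1 at CA4, and goblet genes 1 lost and 5 gained (2.76 and 3.16 expected), with 1 gained at AGR3 and 1 at CLCA1.

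The BMP and TGF-beta list had 7 lost and 8 gained regions (9.07 and 10.3 expected), with 1 lost and 2 gained at BMPR1B and 1 of each at BMP4. Epithelial junction genes had 7 lost and 4 gained (8.43 and 9.14 expected), with 3 lost at PKP2, a desmosome gene, and 1 of each at TJP1. YAP targets had 8 lost and 4 gained (9.17 and 9.67 expected), with 2 lost and 1 gained at YAP1 and 1 gained at AJUBA. Looping factors had 4 lost and 1 gained (3.47 and 3.68 expected), with 2 lost each at STAG1, a cohesin subunit, and SMARCA2, a chromatin remodeller. NF-kB and interferon genes had 0 lost and 4 gained (3.08 and 3.41 expected), with 2 gained at IRF1 and 1 at CCL20. Aryl hydrocarbon receptor targets had 2 lost and 4 gained (3.11 and 3.57 expected), with 2 gained at AHRR and 1 at CYP1B1.

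Of the remaining lists, mesenchymal genes had 3 lost and 3 gained regions (4.45 and 5.26 expected), with CDH2 at 1 of each and LUM at 1 gained. Squamous genes had 2 lost and 0 gained (2.56 and 2.64 expected), at KRT23 and TP63. Housekeeping genes had 1 lost and 4 gained (2.64 and 3.24 expected), with ALAS1 and POLR2A at 1 gained each. Cell cycle genes had 2 and 2 (3.36 and 3.45 expected), with CDK6 at 1 of each and AURKA at 1 gained. Among markers of other cell types, blood and immune genes had 3 lost and 4 gained (3.58 and 4.12 expected), with 2 lost at KIT and 1 gained at GATA3. Fibroblast and endothelial genes had 3 lost and 8 gained (3.28 and 3.93 expected), with 2 lost at ERG and 2 gained at FAP, and their gains were 2.03 times the expected number (unadjusted p = 0.0928, adjusted p = 0.669, permutation test).

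Of the lost regions 4.10% (Wilson 95% interval 3.42 to 4.92) and of the gained regions 4.71% were within 1000 bp of an end of a protein-coding gene, against 19.0% of retained regions. Regions picked by the other pairings were near a gene end in 4.63% to 6.18% of cases (odds ratios 0.207 to 0.281), so a position away from gene ends was not particular to the auxin groups. The odds ratios were 0.182 (p = 7.28e-116) and 0.211 (p = 2.44e-113) by Fisher's exact test, and 0.368 and 0.390 when up to 3000 bp counted as near. Retained regions ranked higher, and within deciles of the rank the odds ratios were closer to 1, at 0.511 (95% interval 0.418 to 0.624) for losses and 0.728 (0.601 to 0.881) for gains. In the same strata the other pairings gave 0.681 (0.503 to 0.922), 0.812 (0.597 to 1.10), 0.894 (0.745 to 1.07) and 0.916 (0.752 to 1.12). The interval for losses with auxin overlaps the first 2 of these, and that for gains overlaps all 4. The strongest gained regions lay on chromosome 6 (112258713 to 112259250, 3996 bp from LAMA4), chromosome 9 (134229216 to 134230309, 69794 bp from WDR5), chromosome 12 (119632167 to 119632765, inside TMEM233), chromosome 21 (10014804 to 10015006, with no protein-coding gene within 100 kb) and chromosome 4 (163297227 to 163298071, 26313 bp from NPY1R).

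The wash comparisons asked whether chromatin went back once auxin was removed. Strong regions that had lost their calls in AID_aux were called again: 181 of 190 (95.3%, Wilson 95% interval 91.2 to 97.5) were called by both AID_wash libraries, and 2 by neither. Retained regions of the same ranks were called by both wash libraries in 97.9% of cases. Strong losses picked by the other pairings were too few to compare, with 4 of 5 and 0 of 1 called by both. The regions near LBH and EIF4EBP1 and inside YAP1 were among the 25 highest-ranked losses, all 25 of which both wash libraries called. AID_wash replicate 1 called 184 and replicate 2 called 185 of the 190.

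Counted directly, 81 strong regions were gained in AID_wash against AID_aux and 10 were lost, while the other pairings gave 1 gained and 1 lost, and 0 gained and 15 lost. Of the 81, 70 were among the 190 strong losses with auxin, which is an overlap of comparisons that share the AID_aux libraries. The 81 gains stood above the other pairings also with the top 30% of each list (15 against 0) and with fixed windows (129 against up to 29), but not with the top 70% (298 against up to 422) or with peaks covering at least 50% of a region (440 against up to 802). The count was 229 without AID_aux replicate 1, 127 without AID_aux replicate 2, 232 without AID_wash replicate 1 and 117 without AID_wash replicate 2. Against AID_ctrl, AID_wash had 7 strong losses and 0 strong gains, and the other pairings gave 0 and 7, and 10 and 1.

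At any strength the return was less clear. Of the 2729 regions lost with auxin, 885 (32.4%, 30.7 to 34.2) were called by both wash libraries and 873 (32.0%) by neither, where 58.1% of retained regions of the same ranks were called by both. Losses picked by the other pairings were called by both wash libraries in 13.1% and 10.8% of cases. The 32.4% was 14.2% without AID_ctrl replicate 1, 13.3% without AID_ctrl replicate 2 and 60.4% without AID_wash replicate 1. Of the 2974 gained regions 1511 (50.8%) were called by neither wash library and 291 (9.78%) by both, and without AID_wash replicate 2 the share not called was 83.4%. The other pairings gave nearly the same for gains, with 51.5% and 48.5% called by neither and 8.86% and 11.8% by both. Where both wash libraries concurred, 67.3% (65.7 to 68.8) of changed regions had the state of AID_ctrl, against 38.0% and 59.6% for regions picked by the other pairings. By direction the share was 50.3% (48.0 to 52.7) for losses, against 22.1% and 17.3%, and 83.9% (82.1 to 85.5) for gains, against 85.3% and 80.4%, so the return of gains was not above the background. The share of 67.3% rests on both AID_ctrl libraries, since it was 36.7% without AID_ctrl replicate 1 and 35.1% without AID_ctrl replicate 2.

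AID_wash against AID_aux gave 3897 lost and 1356 gained regions at any strength, and AID_wash against AID_ctrl 2906 and 745. The other pairings reached 4428 and 3408 in either direction, so none of these counts exceeded the background, although the total of 5253 against AID_aux exceeded their totals of 2529 and 4741. AID_wash replicate 1 has the shortest degron list. With equal list lengths AID_wash against AID_aux had 2027 lost and 2186 gained regions, and AID_wash against AID_ctrl 1487 and 1378, so the excess of losses ended in the first comparison and became small in the second. The other pairings then reached 2138 and 2071. Whichever library was left out the counts rose, to 5250 to 13793 lost and 2072 to 7458 gained against AID_aux and to 4157 to 10547 and 1972 to 7437 against AID_ctrl. CDX2 had 1 lost and 2 gained regions in AID_wash against AID_aux and 0 lost and 0 gained against AID_ctrl. YAP1 had 1 and 1, then 0 and 0. MACROD2 had 3 lost and 4 gained against AID_aux, and 3 lost and 0 gained against AID_ctrl. AHRR had 3 lost and 0 gained against AID_aux, and GATA6 1 lost and 0 gained. Changed regions of both wash comparisons lay near gene ends less often than retained regions (odds ratios 0.175 to 0.312), as did regions picked by the other pairings (0.190 to 0.341), but within deciles of the rank the gains against AID_ctrl did not (0.998, 95% interval 0.745 to 1.34). None of the 34 list tests passed in either comparison (smallest adjusted p = 0.156 with 2 unadjusted p under 0.05, and 0.728 with 0, permutation tests).

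**Figure D2:**
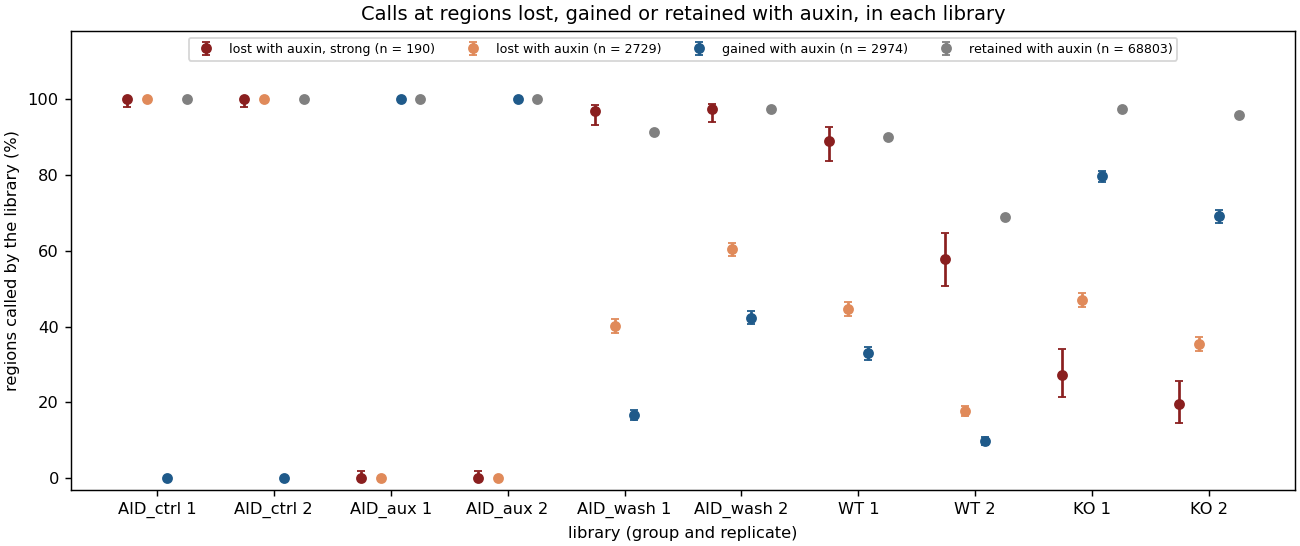
Share of regions called by each library (vertical axis, percent, with Wilson 95% intervals that cover counting error only) for strong regions lost with auxin, all lost, all gained and all retained regions; AID_ctrl and AID_aux values are 0 or 100 by definition. Strong lost regions were called in 96.8% and 97.4% of cases by the AID_wash libraries, 88.9% and 57.9% by WT, and 27.4% and 19.5% by KO.

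The knockout comparison asked what lasting loss of GATA6 does. KO had far more called regions than WT: 30771 regions were gained and 1958 lost, with 50295 retained. Gained regions were most frequent at ASIC2 (25 gained, 0 lost, 3 retained), an acid-sensing ion channel, PLXNA4 (25, 0 and 13), a semaphorin receptor, KAZN (24, 0 and 25), the calcium channel gene CACNA1C (22, 0 and 9), KALRN (21, 1 and 11), TENM4 (21, 1 and 13), CLSTN2 (20, 1 and 13), the nuclear receptor RORA (20, 0 and 24), the growth factor NRG1 (19, 0 and 9) and the transcription factor FOXP1 (19, 0 and 14). GATA6 itself had 6 gained, 0 lost and 12 retained.

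Lost regions were most frequent at CALN1 (5 lost, 3 retained), the phosphodiesterase gene PDE4D (5 and 20, with 18 gained) and RAD51B (5 and 43, with 11 gained). ADGRL2, GPC5, LAMA2, PLEKHG1 and CWH43 had 4 each, against 3, 4, 9, 12 and 19 retained. POTEM (4 lost, 0 retained) and TPTE (4 and 1) belong to families with near-identical copies, and their counts are uncertain because reads may be shared between copies.

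The other pairings of the 4 libraries gave 2408 and 133 regions for both replicate 1 against both replicate 2 libraries, and 535 and 393 for the crossed pairs. The gain in KO therefore exceeded the spread between replicates, and the loss did not. Genotype and cell population coincide here, so other differences between KO and WT cells cannot be told apart from loss of GATA6. The KO lists were also longer than the WT lists, which by itself raises the gained count. Losses were 10964 without WT replicate 1 and 11278 without WT replicate 2, and gains 55615 without WT replicate 1 and 49575 without KO replicate 2. Of the lost regions 15.4% (13.8 to 17.0) and of the gained regions 4.90% (4.67 to 5.15) were near a gene end, against 22.3% of retained regions (odds ratio 0.633 for losses, Fisher's exact p = 5.31e-14, and 0.180 for gains). Without WT replicate 1 the odds ratio for losses was 0.378. Regions picked by the other pairings were near a gene end in 5.60% to 18.5% of cases. On the regions of the degron lists, 828 regions were lost in KO and 4.23% (3.05 to 5.82) of them were near a gene end.

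Epithelial junction and keratin genes gained fewer regions in KO than genes matched only on the number of tested regions did. They had 44 gained regions where 82.5 were expected (adjusted p = 0.00680, permutation test, from the smallest p that 10000 draws can give), and this was the only one of 34 list tests that passed. In this list GRHL2, a transcription factor of epithelial identity, had 9 gained, 1 lost and 11 retained, and LAMA3, a laminin chain of the epithelial basement membrane, 3, 1 and 16. The unadjusted p was under 0.05 in 4 tests. The others were gains at WNT targets (59 against 77.5 expected, adjusted p = 0.262), housekeeping genes (15 against 25.5, adjusted p = 0.254) and cell cycle genes (23 against 35.1, adjusted p = 0.254), by the same permutation test. The gained share was 19.9% of 221 tested regions at junction genes, 20.5% of 73 at housekeeping genes and 23.2% of 99 at cell cycle genes. A low share of gains was thus not particular to junction genes.

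The other lists did not pass in KO. Intestinal transcription factors had 10 lost and 87 gained regions (7.75 and 104.9 expected), with 10 gained at TCF7L2. Among WNT targets, with 5 lost (5.82 expected), TNFRSF19 had 8 gained and CD44 4 gained and 1 lost. Enterocyte genes had 5 lost and 30 gained (2.45 and 34.4 expected), with APOB at 4 gained and ALPI at 1 of each. Goblet genes had 5 and 23 (2.05 and 27.7 expected), with 5 gained at MUC5B and 2 at AGR3, and enteroendocrine genes 1 and 28 (1.04 and 20.5 expected), with 4 gained at NEUROD1 and 3 at CCK. The BMP list had 5 and 80 (6.72 and 95.8 expected), with 6 gained at BMPR1B and 6 at ID3, and the YAP list 7 and 84 (7.36 and 102.7 expected), with 8 gained at CRIM1 and 7 at TEAD1.

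Mesenchymal genes had 3 lost and 63 gained (3.02 and 54.0 expected), with 9 gained at CDH2 and 8 at TGFBI. Squamous genes had 0 and 29 (1.80 and 29.5 expected), with 8 at TP63 and 5 at KRT80, and NF-kB genes 2 and 33 (1.94 and 31.9 expected), with 7 at TNFAIP3 and 5 at IRF1. Aryl hydrocarbon receptor targets had 2 and 42 (2.4 and 40.7 expected), with 10 at KYNU and 6 at TIPARP, and looping factors 3 and 39 (2.33 and 37.0 expected), with 5 each at NIPBL and PDS5B. Housekeeping genes had 6 lost (2.18 expected), with 3 gained each at YWHAZ and TFRC, and cell cycle genes 0 lost (2.54 expected), with 4 gained each at CDK6 and MCM5. Junction genes had 9 lost (7.04 expected). Blood and immune markers had 2 and 32 (2.67 and 42.6 expected), with 7 gained each at PAX5 and RUNX1, and fibroblast and endothelial markers 1 and 34 (2.56 and 38.9 expected), with 5 at CDH5 and 4 at PDGFRA.

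The last comparison asked whether the rapid and the lasting loss of GATA6 closed the same regions. The same regions were called lost in both systems far more often than replicate noise would give. Among 47083 regions that both AID_ctrl and both WT libraries called and that were decided in both systems, 392 were lost with auxin, 481 in KO and 215 in both, which is 53.7 times the number expected for independent lists, where losses picked by the other pairings gave 15.2 and 18.4 times. Of the 392 decided regions lost with auxin 54.8% were lost in KO, against 0.570% of the decided regions retained with auxin. The odds ratio was 91.1 (95% interval 69.0 to 120), while losses picked by the other pairings gave 3.91 (2.26 to 6.77) and 4.84 (2.03 to 11.5). Among strong regions 74 of 98 (75.5%) were lost in KO, against 0.478% of 39969 retained. The 392 are only a part of the 2729 regions lost with auxin at any strength. Of all 2729, the WT libraries called 44.6% and 17.7% and the KO libraries 46.9% and 35.5%, and 406 were gained in KO.

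These 215 regions were assigned to 174 genes, and 37 had no protein-coding gene within 100 kb. Of them 108 (50.2%) lay inside a gene body and 2 (0.930%) near a gene end. Their median length was 786 bp. MACROD2, ADORA2B (an adenosine receptor), BPNT2 and PDE4D had 2 regions each. The LBH, EIF4EBP1 and YAP1 regions were all in this set, and 20 of the 25 highest-ranked losses with auxin were called in both WT and neither KO library. Of the 215, 157 (73.0%, 66.7 to 78.5) were called by both AID_wash libraries. The odds ratio was 52.9 when regions had to overlap reciprocally by 50%, 212 without strata and 252 among strong regions. Without a library it stayed between 33.0 and 76.0, and was more than 1.5 times lower without AID_aux replicate 1 (33.0), AID_aux replicate 2 (34.0), KO replicate 1 (47.7) or WT replicate 2 (48.1). A replicate block, which pools the calls of single libraries with the same replicate number, gave the lowest odds ratio, 12.2 (11.2 to 13.3). No other pairing was run with that block. The count of shared losses was 328 without AID_aux replicate 1 and 571 without WT replicate 2.

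Genes of the lists that belong to this set, named after the values were seen, had 1 such region each. They included CA4, a carbonic anhydrase of the colonocyte surface (2018 bp away, chromosome 17, 60147567 to 60148342), and the BMP receptor gene BMPR2 (inside, chromosome 2, 202529887 to 202530629). YAP1, AMOTL1, CRIM1 and ANXA3 gave the YAP list 4 regions where 0.998 were expected (unadjusted p = 0.0362, adjusted p = 0.615, permutation test), and none of the 17 lists passed, with 1 unadjusted p under 0.05. VIM, STAG1 and KIT were also in the set.

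Gains overlapped more often than independent lists would, but not beyond the background of the other pairings. Of 1327 regions gained with auxin and decided in both systems 1102 (83.0%) were gained in KO where 152.2 were expected, which is 7.24 times as many, and the other pairings gave 8.63 and 7.87 times. The odds ratio was 3.86 (3.30 to 4.50), while gains picked by the other pairings gave 5.13 (3.66 to 7.20) and 3.88 (3.17 to 4.75). Without strata it was 46.0 (39.7 to 53.3), against 63.2 and 54.0 for the other pairings. Without AID_aux replicate 1 the odds ratio was 6.17, without AID_ctrl replicate 2 it was 2.57 and without WT replicate 1 it was 2.22. The count was 2298 and 2022 without AID_ctrl replicates 1 and 2, 2065 and 3228 without AID_aux replicates 1 and 2, and 1735 without WT replicate 1. In opposite directions, 406 regions were lost with auxin and gained in KO, and 9 were gained with auxin and lost in KO.

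**Figure D3:**
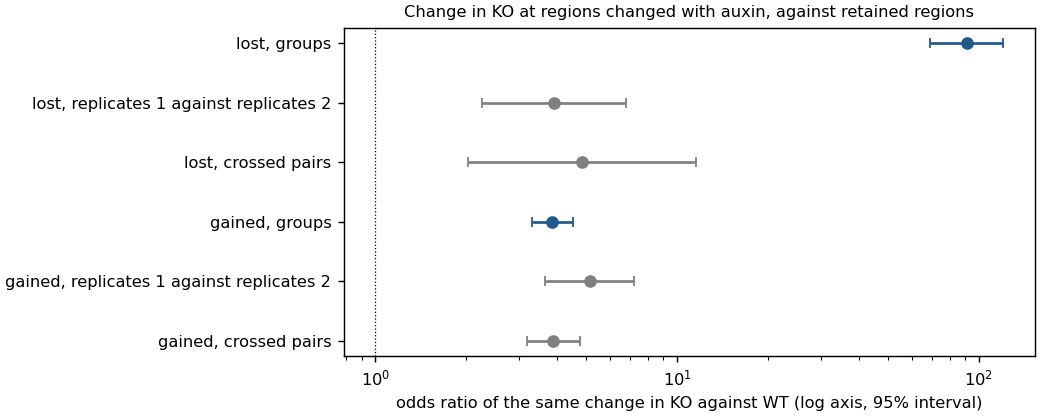
Odds ratio (log axis, points with 95% intervals) of being lost, or gained, in KO against WT for regions lost, or gained, with auxin compared with regions retained with auxin, for the true groups (blue) and the other pairings of the degron libraries (grey). The value for losses (91.1) lies above the background, and that for gains (3.86) lies within it.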

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

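The tests of chance drop-out, of auxin alone and of early gains, and the comparisons that bear on the test of window placement, were chosen after the results they bear on had been seen. The tests of list length and window placement were written before their results.

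The first pattern is the imbalance of the knockout: 15.7 regions were gained per lost region in KO, against 1.09 in AID_aux (odds ratio 14.4, Fisher's exact test). The difference between the systems brought it up. Longer KO lists are a technical explanation that stays open. Among regions strong in the degron lists the ratio was 1.21 (1010 gained, 836 lost), which met the outcome written beforehand for longer lists. However, 97.8% of those regions are called by a WT library and cannot be gained, so the test decides nothing. With all degron regions as the region set the ratio was 21.5 (17772 gained, 828 lost). Of the gained regions 42.7% were called by an AID_ctrl library, that is, in a line with GATA6, and 23.6% by both. An AID_ctrl library called 69.9% of the regions lost in KO and 97.4% of those retained. An early opening after GATA6 loss may contribute, yet the odds ratio of 3.86 for gains lies inside the intervals of the other pairings, so it cannot be told apart from the background.

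The second pattern is that 215 of 392 regions lost with auxin and decided in both systems were also lost in KO. Chance drop-out of weak peaks argues for a small odds ratio, but its lower bound of 69.0 lay above the upper bounds of the other pairings, 6.77 and 11.5. An effect of auxin itself would be absent from KO cells, for which the labels name no auxin. The 215 shared losses were 53.7 times the expected number (46.8 to 61.4, exact Poisson), against 15.2 (8.69 to 24.7) and 18.4 (6.76 to 40.1) for the other pairings. Those pairings hold replicate differences only and do not show what overlap an auxin effect would give. The test therefore cannot exclude auxin for the 215 regions. For the 177 regions lost with auxin that both KO libraries call, an effect of auxin, of the degron clone or of time in KO cells cannot be told apart, since no auxin-treated line without the degron was analysed here. A need for GATA6 to keep the 215 regions open is a hypothesis that these data suggest, found and tested on the same lists, and neither binding of GATA6 there nor closing of these regions under any disturbance was tested.

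The third pattern is that lost regions lay near a gene end in 15.4% of cases in KO and 4.10% with auxin (odds ratio 4.24, p = 7.09e-41, Fisher's exact test), while regions picked by the other pairings of the WT and KO libraries had 5.60% to 18.5%. Windows of 500 bp set differently along broad open regions could produce such losses, since a window counts as lost when those of the other group lie clear of it. Of the KO losses 667 (34.1%) lay within 500 bp of a KO window, and 37.3% of these were near a gene end. Without them the share was 4.03%, which met the outcome written beforehand for window placement. The same step also lowered the share in gained regions (4.90% to 4.21%). It did so too in every set picked by the other pairings (18.5% to 8.52% in the highest). The step therefore does not single out window placement, which cannot be told apart from other causes. On the regions of the degron lists 4.23% of 828 KO losses were near a gene end, close to the 4.10% with auxin, and no biological explanation was tested.

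A further result, not tested as a difference, is that 406 regions were lost with auxin and gained in KO, which is 14.9% of the losses, against 32.1% and 30.7% for losses picked by the other pairings.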

How the results depend on the processing

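The settings for strong regions in the return after wash and in the overlap, those that varied the counts of strong regions, those for KO against WT on degron regions, beside other windows or on regions strong in the degron lists, for the shared losses, for rank deciles and for the replicate block were chosen after the data had been examined, and the rest were planned. Across all alternatives 72 counts and shares were little changed, which for a count means within 1.5 times and for a share within its 95% interval, and 103 moved beyond these bounds. Of values with a test 94 kept direction and call, although 29 of these moved by over 1.5 times and up to 11.9 times, 2 lost their call and 0 changed direction. The odds ratios of lying near a gene end stayed under 1, with the same call, under every setting run, those without a replicate included, except that within rank deciles the gains in AID_wash against AID_ctrl had 0.998 (0.745 to 1.34). Regions picked by the other pairings also had values under 1 without rank deciles (0.207 to 0.281 in AID_aux against AID_ctrl). A kept call therefore does not set the changed regions apart from replicate differences. The odds ratio for shared losses kept its call in every setting run but ranged from 12.2 to 252, and that for shared gains was 46.0 without strata. The call here is only that the interval excludes 1, which the other pairings also met in the main setting. Each count rises when a replicate is left out because fewer libraries have to concur. For the other moves the cause was not tested, except that a stricter or longer list, or a smaller region set, by construction calls fewer or more regions. Depth is unknown, so a region absent from a list may be open below the calling threshold; the 20.0% below rests on 10 regions.

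Only peaks with −log10 q of at least 5: gained regions were 1916 in AID_aux against AID_ctrl and lost regions 2424 in AID_wash against AID_aux. Of regions gained with auxin 45.2% were called by no wash library, the share that reverted was 63.2%, and 687 gains were shared with KO. With equal list lengths AID_wash against AID_aux gave 2027 lost and 2186 gained regions, and AID_wash against AID_ctrl 1487 and 1378, so AID_wash no longer lost more than it gained against AID_aux. Of regions lost with auxin 46.3% were then called by both wash libraries, and of those gained 37.5% by neither. With peaks covering at least 50% of a region, losses were 4496 in AID_aux against AID_ctrl and 4949 in AID_wash against AID_ctrl, 27.0% of losses were called by both wash libraries, and 61.4% reverted.

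Strong regions only: AID_aux against AID_ctrl gave 190 lost and 10 gained, AID_wash against AID_aux 10 and 81, and AID_wash against AID_ctrl 7 and 0. Of these losses with auxin 95.3% were called by both wash libraries and 20.0% of the gains by neither, and 96.3% reverted. Shared losses were 74 and shared gains 2, and the odds ratio for gains, 3.88 (0.709 to 21.3), no longer excluded 1, with 6 regions gained. Among the 215 shared losses 73.0% were called by both wash libraries. With the top 30% in place of the top 50%, strong regions were 41 lost and 0 gained with auxin and 15 gained after wash. With the top 70% they were 627, 240 and 298, with peaks covering at least 50% of a region 963, 368 and 440, and with fixed windows the gains were 22 and 129.

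For KO against WT, fixed windows gave 3853 losses. Only regions strong in the degron lists gave 836 lost and 1010 gained, degron regions as the region set gave 828 and 17772, and 1291 losses lay more than 500 bp from any KO window.

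With each replicate left out in turn, AID_aux against AID_ctrl had 3965 to 7929 lost and 5621 to 11585 gained regions, AID_wash against AID_aux 5250 to 13793 and 2072 to 7458, AID_wash against AID_ctrl 4157 to 10547 and 1972 to 7437, and KO against WT 2262 to 11278 and 31856 to 55615. Strong losses with auxin were 267 to 469, strong gains 52 to 120, and strong gains after wash 117 to 232. The share of losses called by the wash libraries was 13.3% to 60.4%, of gains called by none 35.5% to 83.4%, and the share that reverted 35.1% to 85.3%. It was under 50% without either AID_ctrl replicate. Shared losses were 228 to 571 and shared gains 1135 to 3228, with odds ratios of 33.0 to 76.0 and 2.22 to 6.17.

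Same-numbered libraries showed little shared deviation from the group means. The correlation of these deviations was 0.0105 for AID_ctrl and AID_aux, −0.00809 for AID_ctrl and AID_wash, −0.0332 for AID_aux and AID_wash, and −0.0223 for WT and KO. These values do not show whether same-numbered libraries were prepared together. With a replicate block the odds ratio was 12.2 (11.2 to 13.3) for shared losses and 2.33 (2.23 to 2.43) for shared gains. Both intervals excluded 1, and the value for losses was the lowest of its settings. Its lower bound of 11.2 lies under the upper bound of 11.5 that the crossed pairs had without the block. No other pairing was run with the block, so this setting does not show whether either value exceeds replicate differences. Motif tests, and settings that need scores in the WT and KO lists, were not run.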

Other observations

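The clustering test was written before its result was seen, and the choice of genes named here was made after.

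Regions lost in both systems also lay at known genes outside the lists. EPHA2, a receptor tyrosine kinase, had a region 16153 bp away on chromosome 1 (16171684 to 16172761), and FOSL2, an AP-1 factor, one 25940 bp away on chromosome 2 (28366549 to 28367286). The collagen receptor subunit ITGA2 had one inside the gene on chromosome 5 (53041146 to 53041679), and the matrix protein gene TNC one 34299 bp away on chromosome 9 (115151968 to 115152946). SAV1, a Hippo pathway scaffold, had a region 11579 bp away on chromosome 14 (50679500 to 50680271), and HK2, a glycolytic enzyme, one inside the gene on chromosome 2 (74840103 to 74840655). All 6 of these regions were called by both AID_wash libraries, as were 157 of the 215 in the set. Their calls in the AID_ctrl, AID_aux, WT and KO libraries were fixed by how the set was defined. Nearness does not show which gene a region acts on.

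Neighbouring regions could change together. Of the 215 regions lost in both systems, 4 lay within 100 kb of another, where 1000 random draws matched on rank and nearness to gene ends gave a median of 6 and a middle 95% of 0 to 14. The shared losses were therefore no more clustered than the random draws. The range of the draws is wide, so the test cannot exclude that some neighbouring regions change together.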
